A study of Mus musculus with 20 samples.

How the data were processed

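RNA was extracted with TRIzol and sequenced from poly(A)-selected libraries made with the Universal Plus mRNA-Seq kit with NuQuant, per the labels' protocols. The 8 prefrontal cortex libraries formed batch 1 and the 12 hippocampal libraries batch 2, and each tissue had its own table of gene counts. The authors deposited raw counts per gene and library, with no normalization. fastp, STAR, featureCounts and DESeq2 are named without versions or roles, and build mm10 is named, per the submitters' processing notes. The annotation and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes could therefore be split between them, which leaves class I genes such as H2-D1 and H2-K1, guanylate-binding proteins, haemoglobin genes and the predicted gene Gm21887 uncertain. A misplaced read in such a family would move the counts of single members while changing the total of the family little. The route of nicotine and the sex of the hippocampal animals are not given in the labels.

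Library totals were 36371084 to 46106526 counts in prefrontal cortex and 51969343 to 68196280 in hippocampus. The median 95% confidence interval of a log2 fold change extended 0.29 to either side in prefrontal cortex and 0.22 in hippocampus. The prefrontal cortex table held 55487 gene symbols, of which 120 were repeated, and 24566 genes had 0 counts throughout. The hippocampal table held 57180 Ensembl identifiers, of which 51884 matched the GENCODE vM21 annotation of the mm10 build. The 5296 that did not match held 1.14% of the counts and were tested under their identifiers. Coordinates were taken from the same annotation. All 20 count columns belonged to the libraries described. No 2 libraries of the same group agreed within sampling noise, with a lowest chi-square per degree of freedom of 11.0 over genes with at least 20 counts.

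Libraries were grouped before the data were examined, as were the comparisons, the 36 gene lists, the rule for naming genes and all alternatives except those said to be added after seeing the data. In 4 of 8 prefrontal cortex records the title and treatment field contradicted the column name quoted in the description, and the column name was used. Grouping by title, and the 4 libraries whose labels agree, were alternatives. Records are separate animals only as far as separate libraries show it, so p-values measure the spread between these libraries.

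Each tissue was fitted alone with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-normalised CPM, counts scaled to a common library total. Gene lists were tested with camera on voom values (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 36 lists of a comparison. In prefrontal cortex camera called 18 lists, 0 with an estimated correlation, and fry called 20, of which 16 were shared with camera. The lists called by camera and not by fry were the immediate early and ribosomal protein lists. The tests with an estimated correlation and with fry without single libraries were added after seeing the data. Members that did not pass the expression filter were not counted as measured, and lists needed at least 3 measured members. Overlaps used 2-sided exact Fisher tests. For genes with 0 saline counts a lower bound was taken against 3 counts over the group, and for 1 to 3 counts the ratio is given with an exact 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

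Named genes were the 8 largest rises and 8 largest falls past the threshold with at least 1 CPM in the higher group and no overlap between groups, up to 2 members with the smallest p in each list described (the rule fixed beforehand allowed up to 4), and genes fixed by name. Where no gene passed, the 5 with the smallest p in each direction were given. Other genes named were chosen after their values were seen. Some genes that these rules name are not reported here.

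Alternatives were DESeq2 1.42.0, limma-voom, robust edgeR, RLE and upper-quartile factors, no filter on low counts, a filter of 1 CPM, a test against a 1.2-fold change, each library left out in turn, a replicate block, 1 surrogate variable from sva 3.50.0, covariates for striatal or choroid plexus markers, and the groupings by label. Leaving out the 4 libraries above 1000 CPM of Ttr was added after seeing the data. DESeq2 left 8616 adjusted p values missing in prefrontal cortex and 18568 in hippocampus, and these stayed missing.

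The steps were tested on simulated data with 200 changed genes in each tissue. Counts were drawn independently for each gene, and the changed genes were drawn from those above 1 CPM in saline. In prefrontal cortex edgeR recovered 52 of 100 genes changed 1.5-fold and 85 of 100 changed 2-fold, with 14 false calls among 17207 genes. In hippocampus it recovered 73 and 96, with 6 false calls among 18574 genes, while DESeq2 made 30 false calls there and 38 in prefrontal cortex.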

Results

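Gene expression was measured by poly(A)-selected RNA sequencing in wild-type C57/BL6 mice, an inbred laboratory strain. Prefrontal cortex was taken from males 24 hours after an intraperitoneal injection of lipopolysaccharide (LPS), a bacterial cell wall component that triggers systemic inflammation, at 5 mg/kg (n = 4) or of 0.9% saline (n = 4). Hippocampus was taken 24 hours after nicotine, the agonist of nicotinic acetylcholine receptors, at 0.2 mg/kg (n = 6) or saline (n = 6). The mice were 2 to 6 months old. Sequencing was deep throughout, with 36371084 to 46106526 gene counts per saline library and 39871000 to 42924749 per LPS library in prefrontal cortex. Hippocampal libraries held 51969343 to 68196280 counts with saline and 53145736 to 62982229 with nicotine. Each tissue formed its own batch and its own count table, so the responses to LPS and to nicotine were each tested within a table and were not tested against each other.

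The labels of the prefrontal cortex libraries contradicted themselves. For 4 of the 8 records the title and treatment field named the opposite treatment to the count-table column quoted for the same record. The groups below follow the column names, a choice made before the data were examined, and libraries carry their names from the labels. By column name Samples 1L, 3L, 6L and 8L were saline and Samples 2L, 4L, 5L and 7L were LPS, and the titles of Samples 2L, 4L, 6L and 8L gave the other treatment. Lcn2, which encodes the acute-phase protein lipocalin 2, stood at 254 to 367 CPM (counts scaled to a common library total) in the 4 libraries labelled LPS by column name. In the 4 labelled saline it stood at 0.676 to 13.5 CPM. Under the titles, the libraries called LPS ran from 0.676 to 287 CPM and those called saline from 0.916 to 367 CPM.

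**Figure D1:**
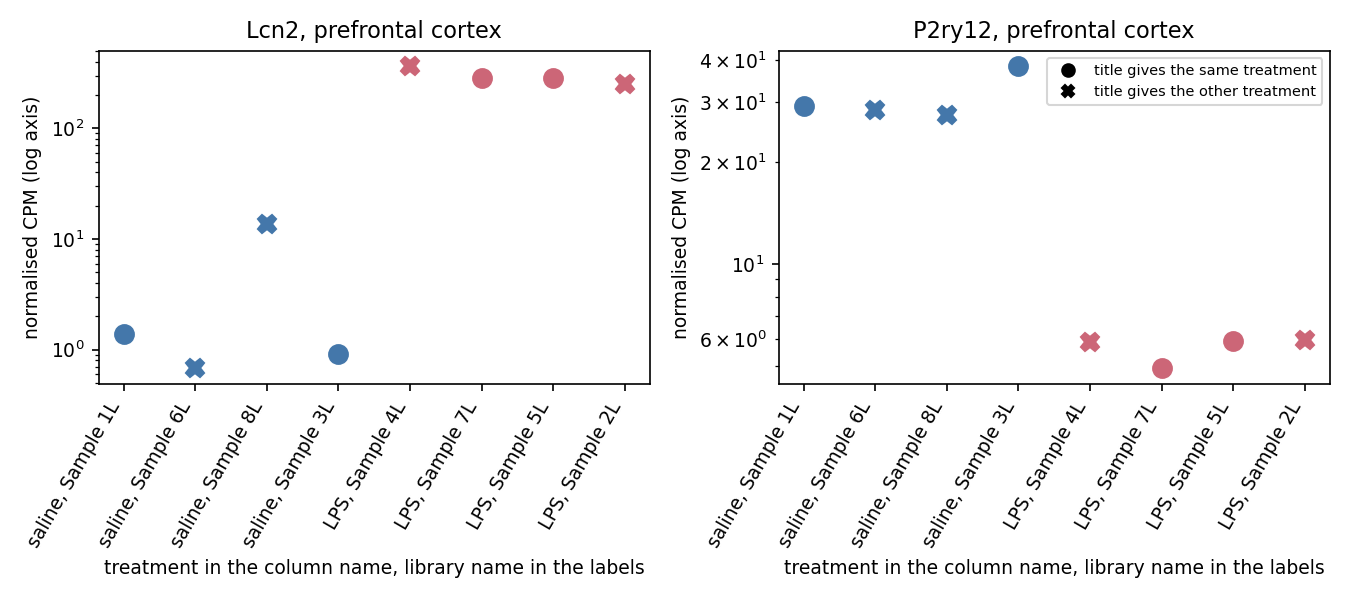
Normalised CPM of Lcn2 and P2ry12 (log axes) in each of the 8 prefrontal cortex libraries, coloured by the treatment in the column name (blue saline, red LPS), with crosses for the 4 records whose title gives the other treatment. Lcn2 reached at least 254 CPM in every library labelled LPS by column name and at most 13.5 CPM in every library labelled saline.

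In prefrontal cortex Saa3 and Lcn2 were higher and P2ry12 was lower with LPS. Saa3, an acute-phase serum amyloid gene, rose from 0.0652 ± 0.0981 to 66.9 ± 12.7 CPM (SD, n = 4 each), a log2 change of 9.80 (SE 0.36, edgeR adjusted p = 5.27e-08). Saline Sample 6L held 10 of the 12 saline counts of Saa3, and without it the ratio was 3974 over 2 counts (95% counting interval 1100 to 32815). Lcn2 rose from 4.12 ± 6.27 to 298 ± 48.1 CPM, a log2 change of 6.17 (SE 0.76), and of 8.24 without saline Sample 8L, which stood at 13.5 CPM. P2ry12, the purinergic receptor of resting microglia, fell from 31.0 ± 5.03 to 5.67 ± 0.509 CPM, a log2 change of -2.45 (SE 0.13). Of 17760 genes tested, 3811 were higher and 3502 lower with LPS, 41.2% in all, and 1003 and 861 of these changed more than 2-fold. The CPM ranges of the groups did not overlap for 6588 genes, against a chance share of 2.86%. Grouping by title and treatment field called 0 genes with edgeR, with 201 at unadjusted p under 0.05, while the 4 libraries whose labels agree called 2826 higher and 2864 lower.

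The 8 largest rises were in Csf3, Mmp3, Saa3, Acod1, Marco, Trem1, Tnf and Hcar2. Mmp3, a matrix metalloproteinase, and Trem1, an amplifying receptor of myeloid cells, had 0 counts over the saline group, so they were at least 241-fold and at least 88.5-fold higher against a floor of 3 counts over the group. Csf3, the granulocyte colony-stimulating factor, had 1 count with saline and 2152 with LPS, a ratio of 2198 (95% counting interval 394 to 86855). Acod1, which makes itaconate in activated macrophages, had a ratio of 1018 (182 to 40260) and Tnf, the cytokine TNF, one of 499 (89.2 to 19767), each also over 1 saline count. The single count lay in Sample 8L for Csf3 and Acod1, which had 0 saline counts without it and were at least 546-fold and 253-fold higher against the floor of 3 counts, and in Sample 1L for Tnf, which was at least 127-fold higher without it. The scavenger receptor gene Marco had 3 saline counts and a ratio of 669 (229 to 3247). Hcar2, a receptor for hydroxybutyrate and niacin, had a log2 change of 6.28 (SE 0.52), and without saline Sample 8L a ratio of 182 over 3 saline counts (62.1 to 886). The largest falls were in Slc38a5, an amino acid transporter (log2 change -4.54, SE 0.45), AU021092 (-4.25, SE 0.50), Crybb1, a crystallin gene also expressed by microglia (-4.00, SE 0.31), Slc26a7, an anion transporter (-3.93, SE 0.42), and Slc47a1, an organic cation exporter (-3.82, SE 0.34). Another 3 of the 8 largest falls were in predicted genes.

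Most members of the endotoxin, interferon, antigen presentation and complement lists rose. Of the endotoxin response list, 24 of 25 measured members rose over all genes tested and 24 adjusted over the list alone, with the adhesion molecule gene Icam1 at 3.32 ± 0.223 CPM in saline and 29.2 ± 2.69 in LPS. Il1b, encoding interleukin-1 beta, had a log2 change of 3.10 (SE 0.38). The interferon-stimulated list had 34 risers of 36 (34 adjusted over the list alone), among them Irf7, a driver of interferon expression (3.41, SE 0.16), Gbp2, a guanylate-binding protein (4.05, SE 0.20), and Cxcl10, a lymphocyte-attracting chemokine (4.82, SE 0.46). The camera adjusted p was 1.38e-14 for the endotoxin list and 3.78e-21 for the interferon list, and neither call held with an estimated correlation (adjusted p = 0.206 and 0.0990). In the antigen presentation list 12 of 17 rose and 4 fell (12 and 5 adjusted over the list alone), with Tap1, a peptide transporter, at 3.25 (SE 0.17) and Psmb8, an immunoproteasome subunit, at 2.06 (SE 0.11). The 4 that fell, H2-Eb1 (-2.19), H2-Aa (-1.91), H2-Ab1 (-1.70) and H2-DMa (-0.38), belong to the class II pathway, which presents peptides to helper T cells. Complement genes rose in 9 of 14 cases and fell in 1 (likewise adjusted over the list alone), led by the anaphylatoxin receptor genes C3ar1 (2.58, SE 0.16) and C5ar1 (3.51, SE 0.33). Camera gave an adjusted p of 0.000300 for each of these lists, lost with an estimated correlation (adjusted p = 0.378 and 0.418). Markers of peripheral leukocytes moved with these lists, with a mean log2 CPM of -0.40 to 0.64 in saline and 0.87 to 1.69 in LPS libraries, and 3 of 6 measured markers rose and 1 fell (camera adjusted p = 0.109, and 0.00671 to 0.0455 without Sample 1L, 3L, 6L, 7L or 8L). With an estimated correlation the adjusted p of the leukocyte list was 0.517, and 0.229 to 0.434 without those libraries, while fry, which asks whether the genes of a list move 1 way on balance and not whether they move more than other genes, gave 0.0175.

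Microglial genes moved apart by state. Of 18 homeostatic microglia genes, 13 fell and 1 rose, the same counts adjusted over the list alone, including the fructose transporter gene Slc2a5 (-3.19, SE 0.23) and Tmem119, a microglial surface marker (-0.91, SE 0.16). Of 28 genes of activated microglia, 15 rose and 2 fell, again the same adjusted over the list alone, with the scavenger receptor gene Msr1 at 5.71 (SE 0.34) and Lgals3bp, a galectin-binding protein, at 1.63 (SE 0.10). Trem2, a lipid-sensing microglial receptor, fell (-1.28). The camera adjusted p was 1.22e-06 and 0.000842, and with an estimated correlation the adjusted p was 0.206 and 0.311. Bulk libraries do not separate the number of microglia from the transcript level per cell.

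Most genes of the astrocyte reactivity lists rose while several mature astrocyte markers fell. Several members of these lists, Steap4 and Cd14 among them, are also in the endotoxin list, and Fkbp5 is also in the glucocorticoid list. Bulk libraries do not show which cells expressed them. Of 13 genes shared by reactive states, 10 rose and 1 fell, of 12 LPS-type genes, some of them also interferon-stimulated, class I or complement genes, 10 rose and 0 fell, and of 11 ischaemia-type genes 8 rose and 1 fell, with the same counts adjusted over each list alone. Timp1, a metalloproteinase inhibitor, had a log2 change of 4.80 (SE 0.24), Steap4, a metalloreductase, 4.68 (SE 0.24), the endotoxin co-receptor gene Cd14 2.95 (SE 0.23) and Tm4sf1 1.40 (SE 0.14). Gfap, the astrocyte intermediate filament, rose from 198 ± 7.77 to 496 ± 82.6 CPM (log2 change 1.33, SE 0.11). The camera adjusted p of these lists was 6.25e-07, 1.34e-06 and 0.00460, and with an estimated correlation the adjusted p was 0.311, 0.206 and 0.418. Of 15 astrocyte markers, 7 fell and 3 rose (8 and 3 adjusted over the list alone), including the gap junction gene Gja1 (-0.52, SE 0.07) and the neurotensin receptor gene Ntsr2 (-0.59, SE 0.08), with a camera adjusted p of 0.109. Of 23 endothelial and barrier genes, 7 rose and 7 fell (the same adjusted over the list alone), with a camera adjusted p of 0.437. Fry gave an adjusted p of 0.00223 for the astrocyte markers and of 0.0253 for the endothelial list. The thyroid hormone transporter gene Slco1c1 (-1.95, SE 0.11) and Itm2a (-1.99, SE 0.15) fell.

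Most glucocorticoid-responsive and clock genes rose. Of 26 glucocorticoid response genes 24 rose, also adjusted over the list alone, among them Fkbp5, a chaperone regulating the glucocorticoid receptor, from 46.4 ± 8.11 to 192 ± 15.4 CPM (log2 change 2.05, SE 0.12), and the metallothionein gene Mt1 (1.91, SE 0.12). The camera adjusted p was 1.38e-14 and, with an estimated correlation, the adjusted p was 0.259. Of 17 clock genes 10 rose and 0 fell, also adjusted over the list alone, among them the transcription factor gene Tef (0.66, SE 0.07) and the repressor gene Cry2 (0.57, SE 0.09), with an adjusted p of 0.00387 by camera and of 0.311 with an estimated correlation.

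Most members of the activity-regulated, oligodendrocyte-lineage and chaperone lists fell, as did 36 of 84 respiratory chain genes. Of 26 immediate early genes 17 fell and 0 rose (18 fell adjusted over the list alone), with the neurotrophin gene Bdnf at -1.51 (SE 0.12) and the nuclear receptor gene Nr4a3 at -1.97 (SE 0.22). The mean log2 CPM of this list was 6.39 in saline Sample 6L and 5.18 to 5.45 in the other saline libraries. Of 20 oligodendrocyte and myelin genes 13 fell and 0 rose (also adjusted over the list alone), including Ugt8a, which makes myelin galactolipids, from 32.4 ± 6.15 to 8.11 ± 1.41 CPM, and the lineage transcription factor gene Sox10 (-0.88, SE 0.10). Of 10 oligodendrocyte precursor genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Matn4 at -1.41 (SE 0.11) and Gpr17, a receptor of maturing precursors, at -2.32 (SE 0.31). Of 23 chaperone and heat shock genes 14 fell and 1 rose (the same adjusted over the list alone), with Hsph1 at -0.90 (SE 0.09) and Chordc1 at -1.58 (SE 0.22). Of 84 nuclear respiratory chain genes 36 fell and 1 rose (the same adjusted over the list alone), with Ndufb2, a complex I subunit, going from 17.7 ± 1.18 to 8.86 ± 0.826 CPM and the ATP synthase subunit gene Atp5e at -0.84 (SE 0.11). Camera gave adjusted p of 2.09e-05, 6.87e-06, 0.0226, 0.000835 and 2.26e-06 for these lists in the order named. With an estimated correlation the adjusted p was 0.517, 0.418, 0.273, 0.517 and 0.517, and fry gave 0.0587 for the immediate early list.

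**Figure D2:**
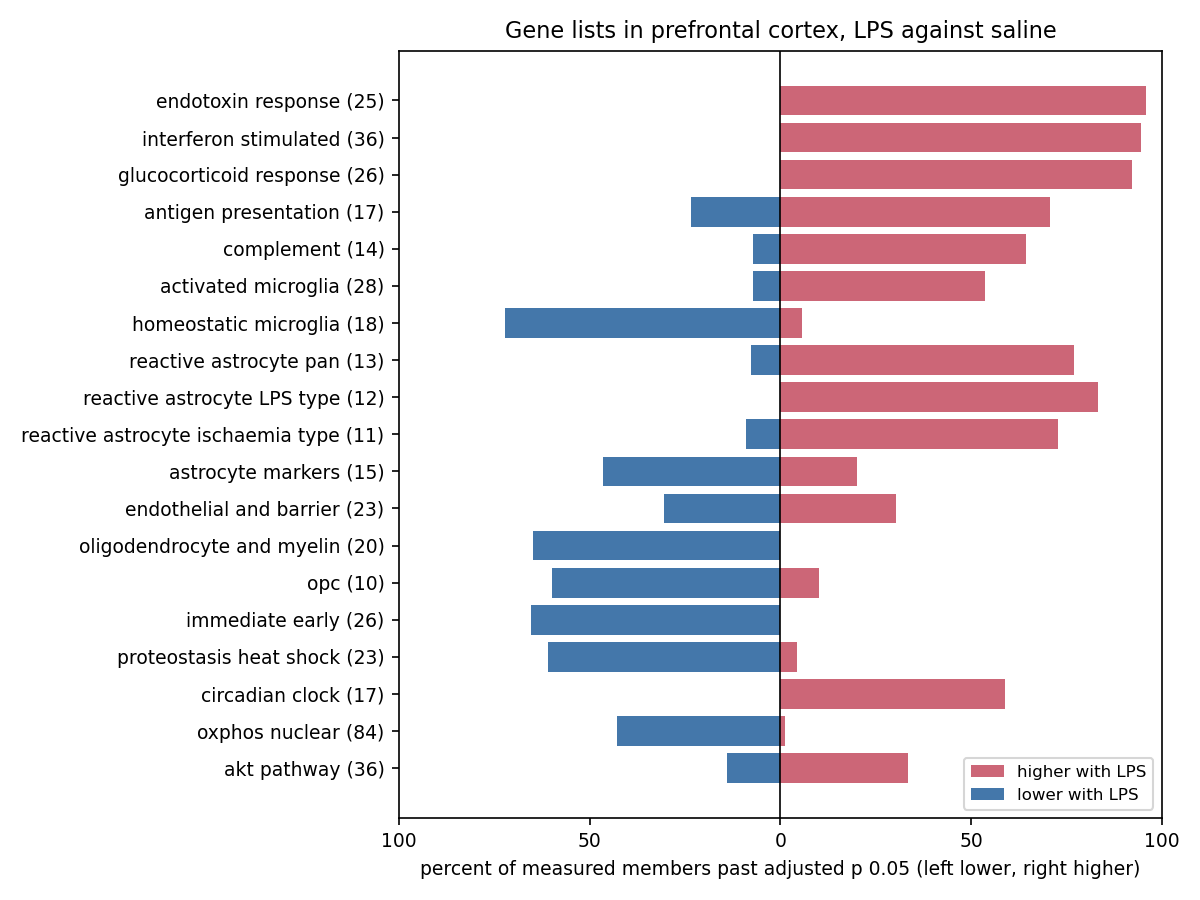
Percent of the measured members of each gene list (number measured in brackets) with edgeR adjusted p under 0.05 in prefrontal cortex, higher with LPS to the right (red) and lower to the left (blue). In the interferon list 34 of 36 members were higher, and in the homeostatic microglia list 13 of 18 were lower.

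Neuronal lists moved in both directions, beside 41.2% of all genes tested that passed the threshold (3811 higher and 3502 lower). Of 30 excitatory synapse genes 6 rose and 8 fell (6 and 10 adjusted over the list alone), with Grin1, the obligatory NMDA receptor subunit, at 0.48 (SE 0.07) and the glutamate receptor gene Grm3 at -0.79 (SE 0.10). Of 19 inhibitory neuron genes 3 rose and 6 fell (the same adjusted over the list alone). Dlx1, an interneuron transcription factor gene, had -0.98 (SE 0.24), and its call was lost in the 4 libraries with agreeing labels (-0.55, adjusted p = 0.0726, against 1.36e-05 to 1.00 over all alternatives). Of 26 nicotinic and cholinergic genes 3 rose and 6 fell (3 and 5 adjusted over the list alone), including Tmem35a, a nicotinic receptor chaperone (-0.68, SE 0.09), and Bche, butyrylcholinesterase (-1.75, SE 0.29). The camera adjusted p was 0.802, 0.109 and 0.411, and 0.0410 for the inhibitory neuron list without LPS Sample 7L (adjusted p = 0.429 there with an estimated correlation). Fry gave the nicotinic and cholinergic list an adjusted p of 0.0285, and the inhibitory neuron list 0.0634, or 0.0336 without Sample 7L. Markers of striatum, a neighbouring region, varied strongly between libraries, with a mean log2 CPM of 3.14 to 5.79 in saline and 2.87 to 5.99 in LPS, and 0 of its 15 genes passed the test (camera adjusted p = 0.485, and 0.00252 without LPS Sample 7L, where the adjusted p with an estimated correlation was 0.599).

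Akt2, a kinase of insulin and growth factor signalling, fell in prefrontal cortex while Akt1 did not pass the threshold. Akt2 (chromosome 7, 27591552 to 27640826, mm10) fell from 101 ± 1.57 to 56.5 ± 5.77 CPM, a log2 change of -0.84 (SE 0.08, edgeR adjusted p = 1.88e-05). Akt1 (chromosome 12, 112653821 to 112674884) stood at 184 ± 4.68 and 201 ± 9.16 CPM (0.13, SE 0.06, adjusted p = 0.102). Of 36 genes of the Akt pathway 12 rose and 5 fell (the same adjusted over the list alone), led by the related kinase gene Sgk1 (1.70, SE 0.22), with a camera adjusted p of 0.292.

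In hippocampus no gene passed the threshold 24 hours after nicotine. With edgeR, 0 of 18873 genes were higher and 0 lower, and the smallest adjusted p was 0.555. At unadjusted p under 0.05 there were 1577 genes, 735 higher and 842 lower, where evenly spread p-values would give 944. Over 100 splits drawn of the 12 libraries, the real one included, the median was 728 and 16 gave at least 1577. DESeq2 called 8 higher and 7 lower, and limma-voom called 0. The genes called higher by DESeq2 were Pcdh11x, Akap12, Tox, Slc8a3, Cit, Efna5, Hrh2 and Meis2. Those called lower were Plk5, Rasl10a, Calb1, Synpr, Slc26a10, Gpr27 and 1 predicted gene. The median 95% confidence interval of a log2 change extended 0.22 to either side. In simulated counts for these 12 libraries, edgeR recovered 73 of 100 genes changed 1.5-fold and 96 of 100 changed 2-fold, with 6 false calls. DESeq2 recovered 84 and 97 there, with 30 false calls. The simulation held no variation shared between genes of a library and no change below 1.5-fold. It also held 200 changed genes, and the adjusted threshold is stricter when fewer genes change. It therefore does not give the power for smaller changes or for a response of few genes.

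The genes with the smallest unadjusted p in each direction are given as values that did not pass. Plk5, a polo-like kinase expressed in brain, stood at 19.5 ± 1.98 CPM with saline and 11.7 ± 2.91 with nicotine (SD, n = 6 each), a log2 change of -0.73 (SE 0.13, edgeR adjusted p = 0.555). It passed without nicotine library 5 (-0.85, adjusted p = 0.0306) and without the 4 libraries richest in choroid plexus transcripts (-0.85, adjusted p = 0.0488), a setting chosen after seeing the data. Over all alternatives its adjusted p ran from 0.00164 with DESeq2 to 0.862 without nicotine library 6. The other low values were Slc26a10 at -0.61 (SE 0.14), Rasl10a at -0.43 (SE 0.08), the synaptic vesicle gene Synpr at -0.40 (SE 0.09) and Calb1, the calcium buffer calbindin, at -0.34 (SE 0.07). The high values were Cit at 0.55 (SE 0.12), the protocadherin gene Pcdh11x at 0.43 (SE 0.08), Akap12, a kinase anchor, at 0.42 (SE 0.09), Tox at 0.42 (SE 0.09) and the sodium-calcium exchanger gene Slc8a3 at 0.41 (SE 0.09).

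The nicotinic receptor and activity genes fixed beforehand did not pass in hippocampus. Chrna4, a main subunit of brain nicotinic receptors, stood at 25.8 ± 6.79 and 34.1 ± 6.26 CPM (0.40, SE 0.16, edgeR adjusted p = 0.556). Its partner Chrnb2 had 0.11 (SE 0.10), Chrna7 0.13 (SE 0.14) and Chrna5 -0.09 (SE 0.14). The activity genes Fos (0.20, SE 0.32), Arc (0.02, SE 0.28) and Bdnf (-0.07, SE 0.08) did not pass, and neither did Akt1 (-0.08, SE 0.06) or Akt2 (-0.02, SE 0.06). In the nicotinic and cholinergic list 17 of 25 measured genes had positive values, 0 passed over all genes and 1, Chrm2, a muscarinic receptor gene (0.39), rose adjusted over the list alone. Camera gave this list an adjusted p of 0.0546, and of 0.0249 to 0.0435 without saline 1, 3 or 6 or nicotine 3. With an estimated correlation the adjusted p was 0.678, and 0.669 to 0.794 without those libraries.

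**Figure D3:**
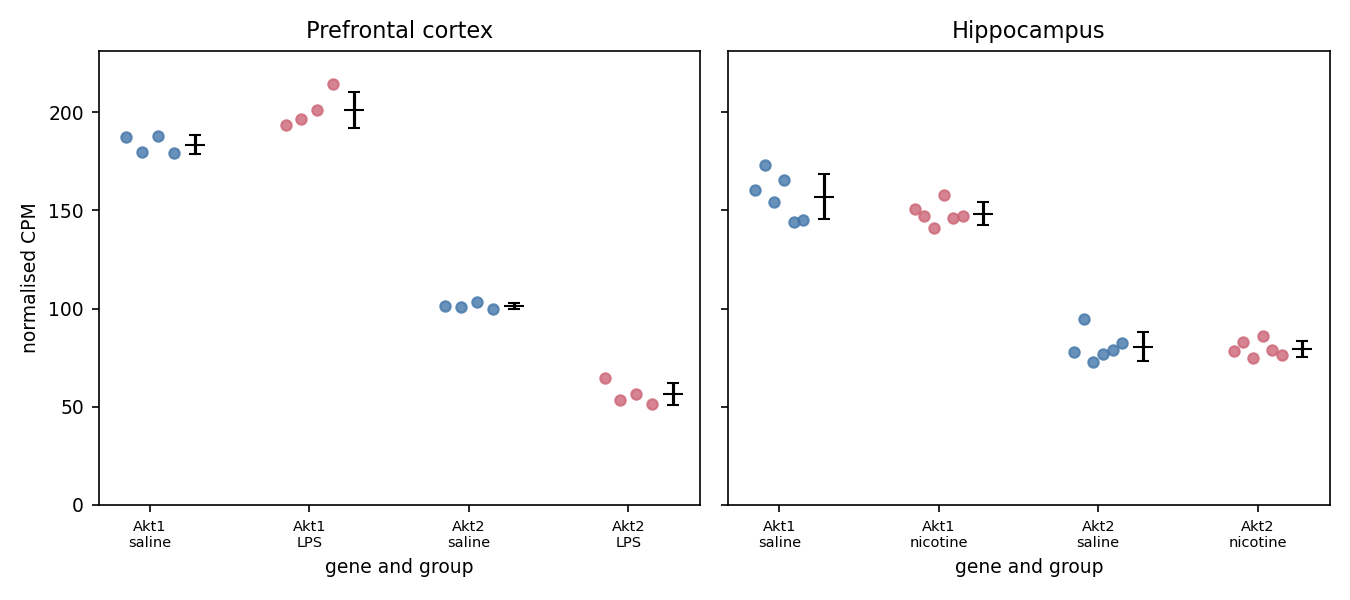
Normalised CPM of Akt1 and Akt2 per library in prefrontal cortex (saline and LPS, 4 libraries each) and hippocampus (saline and nicotine, 6 libraries each), with the mean and SD in black beside the points. Akt2 in prefrontal cortex was 101 CPM with saline and 56.5 CPM with LPS on average.

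**Figure D4:**
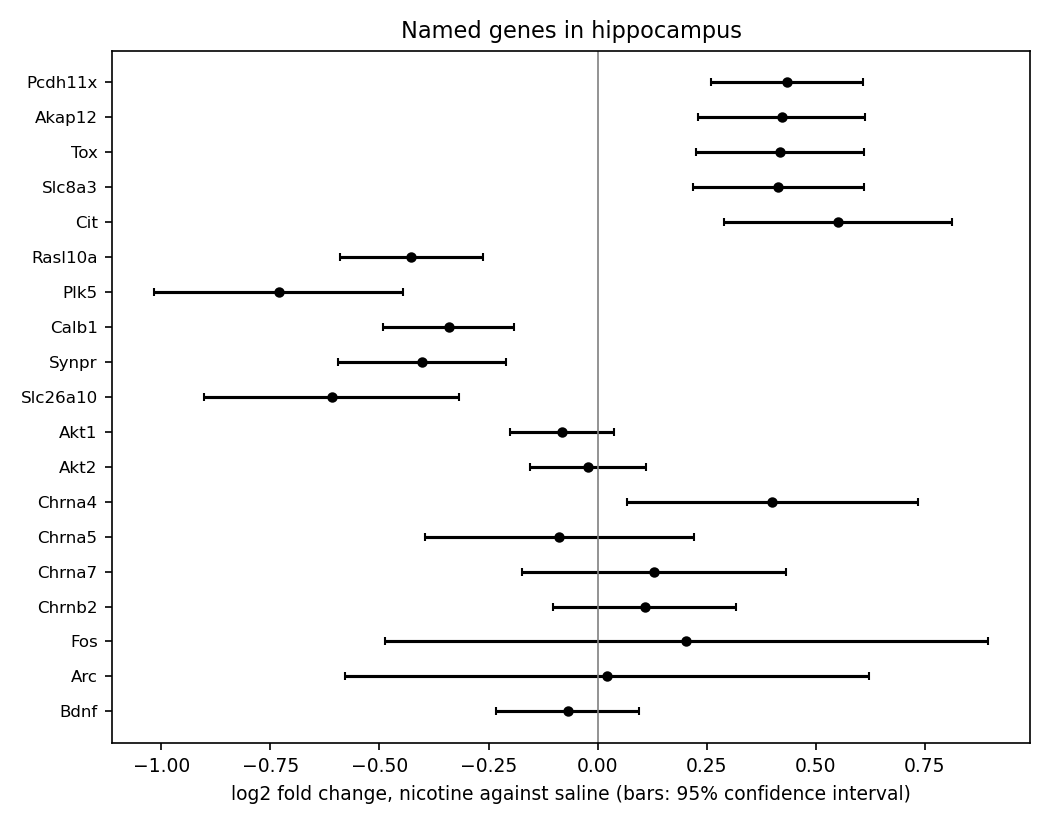
Log2 fold change with its 95% confidence interval, nicotine against saline in hippocampus, for the 5 genes with the smallest p in each direction and 9 of the genes fixed beforehand. None passed the adjusted threshold, and the smallest adjusted p was 0.555.

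At the level of lists, camera with its preset correlation called 9 in hippocampus, 0 held with an estimated correlation, and fry called 0 (lowest adjusted p = 0.529). Ribosomal protein genes were lower (78 of 81 negative, median -0.24), as were respiratory chain genes (79 of 85, median -0.11), chaperone genes (18 of 23, median -0.11), activated microglia genes (23 of 25, median -0.13) and homeostatic microglia genes (15 of 18, median -0.10). Inhibitory neuron genes were higher (17 of 19, median 0.16), as were endothelial (18 of 23, median 0.13), pericyte (11 of 12, median 0.09) and excitatory synapse genes (22 of 30, median 0.08). Saline 2 was the highest library for 73 of 81 ribosomal, 55 of 85 respiratory chain, 19 of 25 activated and 14 of 18 homeostatic microglia genes and the lowest for 21 of 30 excitatory synapse genes. Nicotine 3 was the lowest library for 50 of 81 ribosomal and 39 of 85 respiratory chain genes, and nicotine 2 for 24 and 25 of them. Without saline 2 the ribosomal median was -0.14. The camera calls of activated microglia (median 0.00336, adjusted p = 0.541), homeostatic microglia (-0.0254, adjusted p = 0.541) and excitatory synapse genes (0.0339, adjusted p = 0.307) were then lost. The activated microglia call was also lost without nicotine 1 or 3 (adjusted p = 0.0598 and 0.0666), the homeostatic call without saline 4 or 6 or nicotine 1, 3, 5 or 6 (0.0697 to 0.178), and the pericyte call without saline 1, 3, 4 or 6 or nicotine 2, 4 or 6 (0.0670 to 0.124). The activated microglia median was -0.21 without nicotine 5, and without nicotine 2 the endothelial median was 0.0852 and the chaperone median -0.0695. With an estimated correlation the adjusted p was 0.678 for ribosomal, respiratory chain, chaperone, inhibitory neuron, endothelial and pericyte genes, 0.889 for activated microglia, 0.946 for homeostatic microglia and 0.864 for excitatory synapse genes. Mitochondrially encoded genes took 11.6% of the counts of nicotine library 2 and 5.60% to 9.10% in the other hippocampal libraries. In each of these lists 0 members passed over all genes or adjusted over the list alone. Choroid plexus transcripts differed widely between libraries of both groups, with Ttr, the transthyretin gene of this tissue, from 15.2 to 3807 CPM in saline and 31.5 to 2197 CPM in nicotine libraries.

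The overlap of LPS and nicotine calls was 0 genes, since edgeR called none with nicotine. At unadjusted p under 0.01 among 16650 genes tested in both tables, 19 were higher in both (25.4 by chance, exact Fisher p = 0.185) and 41 lower in both (26.6 by chance, exact Fisher p = 0.00363). The Fisher test treats genes as independent, which they are not, so its p does not measure the spread between libraries. With DESeq2 calls, Akap12 was shared upwards (1.18 genes by chance) and Synpr and Rasl10a downwards (0.80 by chance, exact Fisher p = 0.186). The log2 changes correlated weakly across genes, which are not independent replicates (Spearman rho 0.0617).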

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

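All tests of explanations below were chosen after the result was seen, except the counts over other splits of the libraries. Of 160 groups of values, 20 held a library far from the others by Dixon's test. Chance gives about 1 in 20 groups only for independent normal values, which CPM of related genes are not, so no conclusion is drawn from the excess.

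The first pattern is the contradiction between titles and column names. Were the titles right, every library titled LPS would hold more Lcn2 than every library titled saline, but the lowest titled LPS stood at 0.676 CPM and the highest titled saline at 367 CPM. This argues against the titles as the true treatments. All 8 records quoted the column at their own position in the table, so a link by position may account for the mismatch. The same count would arise if the columns were entered with care and only the titles were wrong. Of the 35 splits of the 8 libraries, 1, the real one, called as many as 7313 genes and the highest other split called 0. Every other split puts libraries of both column-name treatments on each side, so its low count was largely set in advance. Ranking first of 35 splits is the most that this count can show, and it cannot exclude chance.

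The second pattern is saline Sample 8L, where Lcn2 stood at 13.5 CPM against 0.676 to 1.39 in the other saline libraries. RNA or reads from an LPS library would bring Saa3 at 2.81 CPM, but it stood at 0.0238 CPM, which argues against that source. A set of 27 genes other than Lcn2, Saa3 among them, had at least 1 CPM with LPS and at least 30 times their level in the other saline libraries. Carry-over would bring each at the share of the LPS level that Lcn2 reached (4.20%). Timp1, Cxcl1, Csf3, Marco and Msr1, at 10.3 to 18.1 CPM with LPS, reached only -0.41% to 1.93%. The lower quartile of the set was 0.12%, which argues against carry-over for these genes too. Of the set, 10 nevertheless reached the share of Lcn2, among them Tmem252 (20.4%), and the median was 2.62%. A glucocorticoid-type response of this animal may be involved, since 17 of the 25 other glucocorticoid list members were highest in it, and Plin4 stood at 19.0 CPM against 1.62 to 4.80 CPM. No group in the design gives a biological explanation to test, and genes of the blood (5 of 7), complement (8 of 14), clock (9 of 17), endotoxin (12 of 24) and interferon lists (15 of 36) were often highest there as well, against 21.2% of all genes, so the pattern is not particular to glucocorticoid genes.

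The third pattern is a set of lower genes with nicotine, several of them known in dentate granule cells, although edgeR called 0 (1577 at unadjusted p under 0.05, DESeq2 15 and limma-voom 0). The 7 genes called lower by DESeq2 had a median log2 change of -0.43. With choroid plexus markers as a covariate it was -0.43 (99.7% kept), which argues against choroid plexus as the source. With 6 dentate markers it was -0.34, but those markers were picked after they were seen to be lower. With the dentate and newborn neuron list fixed in advance 95.6% was kept. That list is mixed, with 6 of 12 measured members positive, and it shares Prox1 and Dsp with the 6 markers. Neither covariate measures the dentate share alone, so a smaller dentate share and an effect of nicotine cannot be told apart. In the hippocampus 16 of 100 splits drawn, the real one included, gave at least 1577 genes at unadjusted p under 0.05. The highest other split gave 2853, so chance cannot be excluded.

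The split of the hippocampal libraries that called the most genes called 73 past the adjusted threshold and another called 5, where the real split called 0 with edgeR (1577 at unadjusted p under 0.05, DESeq2 15 and limma-voom 0). Both put the 4 libraries rich in Ttr on one side, but the 4 other splits drawn that did so called 0 with edgeR (981 to 2492 at unadjusted p under 0.05), which leaves the source of these calls open.

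Among LPS libraries, Sample 7L stood apart with Marco at 2.71 CPM (14.3 to 16.0 in the others), Psmb8 at 13.7 (16.1 to 16.4) and P2ry12 at 4.91 (5.89 to 5.97). Sample 2L stood apart with Cd14 at 9.21 CPM (15.2 to 16.4), Tm4sf1 at 9.60 (13.4 to 13.5), Mt1 at 469 (640.0 to 657), Sox10 at 28.6 (25.1 to 25.4) and Gpr17 at 19.6 (6.71 to 7.61). Among saline libraries, Sample 6L was highest for Saa3 at 0.211 CPM, Gja1 at 217 (197 to 200.3), Tmem35a at 70.8 (63.3 to 64.1) and Hsph1 at 355 (271 to 285). Sample 3L stood apart with Icam1 at 2.99 CPM (3.42 to 3.45), P2ry12 at 38.5 (27.6 to 29.3) and Ntsr2 at 84.2 (at most 96.8 in the others). A single count put Csf3 and Acod1 at 0.0238 CPM in Sample 8L and Tnf at 0.0257 CPM in Sample 1L, with 0 in the other saline libraries. Chrnb2 in hippocampal saline library 2 stood at 38.4 CPM (56.3 to 64.0).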

How the results depend on the processing

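The alternative without the 4 choroid-rich libraries, and list tests with an estimated correlation or fry without single libraries, were chosen after the result was seen. In prefrontal cortex the counts higher and lower stayed within 1.5 times of 3811 and 3502 with DESeq2 (4140 and 3778), limma-voom, robust edgeR, other factors, other filters, 1 surrogate variable and the striatal covariate. Leaving out 1 library gave 2878 to 4327 higher and 2825 to 4154 lower. The test against a 1.2-fold change gave 2033 and 1922, since it asks for a larger effect. With the replicate block the counts were 3144 and 2920, and 0 and 0 in hippocampus (edgeR, 1649 at unadjusted p under 0.05). Correlations of deviations between libraries of the same number were -0.16 to -0.03 in prefrontal cortex and -0.17 to 0.44 in hippocampus, and only saline 5 correlated best with its own number. These values did not show a pairing by number, but they cannot exclude it. The block changed no call of a named gene or list. With the 4 libraries of agreeing labels, 61 of 62 named genes kept direction and call, and Dlx1 did not. The blood list lost its call there and in 3 other settings, and the ribosomal list there and without LPS Sample 2L or saline Sample 3L.

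Grouping by title and treatment field called 0 higher and 0 lower with edgeR (201 at unadjusted p under 0.05), DESeq2 and limma-voom not being run on it. By construction it puts libraries of opposite column names together. Log2 changes then reversed for Mmp3 (-0.87), Saa3 (-0.37), Marco (-0.77), Trem1 (-0.42), Slc38a5 (0.21), AU021092 (0.17), Gm34838 (0.54), Crybb1 (0.11), Gm12940 (0.65), Icam1 (-0.0325), Irf7 (-0.0245), Gbp2 (-0.29), Psmb8 (-0.10), C3ar1 (-0.11), C5ar1 (-0.35), Slc2a5 (0.17), Msr1 (-0.73), Lgals3bp (-0.23), Timp1 (-0.26), Steap4 (-0.22), Gja1 (0.0485), Ntsr2 (0.11), Bdnf (0.0852), Nr4a3 (0.52), Matn4 (0.0167), Gpr17 (0.12), Dlx1 (0.39), Tmem35a (0.15), Hsph1 (0.10), Ndufb2 (0.0142), Atp5e (0.15), Lcn2 (-0.0892) and Il1b (-0.12). List medians or tests reversed for interferon (-0.12), antigen presentation (-0.22), complement (-0.30), activated microglia (-0.14), pan-reactive (-0.0877) and LPS-type astrocyte (-0.0949), immediate early (0.66), inhibitory neuron (0.16), oligodendrocyte (-0.00618), precursor (0.0407), chaperone (0.0899), blood (0.24), respiratory chain (-0.00864), ribosomal (0.010) and mitochondrially encoded genes (-0.20).

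In hippocampus DESeq2 called 8 higher and 7 lower where edgeR called 0 (1577 at unadjusted p under 0.05) and limma-voom 0. Leaving out 1 library gave 0 to 0 higher and 0 to 1 lower, the 1 being Plk5 without nicotine 5, and leaving out nicotine 6 moved the count at unadjusted p to 1029. Without the 4 choroid-rich libraries 1 gene was lower and 2602 stood at unadjusted p under 0.05. The blood list kept a positive median (0.33, and 0.54 without nicotine 5), but camera's direction went from lower (adjusted p = 0.956) to higher (0.0449) without that library, where the adjusted p with an estimated correlation was 0.729. The choroid plexus list reversed from -0.51 to 0.0204 with 1 surrogate variable, and the cause was not tested. Overlap with LPS rose from 0 to 60 at unadjusted p under 0.01 and to 3 with DESeq2. The covariate for Y-linked genes was not run, since all hippocampal libraries expressed them.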

Other observations

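No test in this part was planned beyond those of the gene lists, and single genes were named after their values were seen. In prefrontal cortex, genes typical of other tissues both rose and fell. Among 6 measured leukocyte genes 3 rose, the neutrophil genes S100a8 (1.83) and Ngp (2.62) and the protease gene Mmp9 (1.56), and Lyz2 fell (-0.76), with a camera adjusted p of 0.109 that was 0.00671 to 0.0455 without Sample 1L, 3L, 6L, 7L or 8L (adjusted p = 0.229 to 0.434 there with an estimated correlation). Among 15 fibroblast and meningeal genes 6 fell and 2 rose, with Slc22a6 (-2.22) and Ogn (-2.13) lower and Dcn, the proteoglycan decorin, higher (1.22, list adjusted p = 0.109, and 0.0338 and 0.00123 without Samples 4L and 8L, where the adjusted p with an estimated correlation was 0.644 and 0.482 and fry gave 0.234 and 0.0271). Of 7 blood genes 4 fell, including the haemoglobin gene Hbb-bt (-1.79), with a camera adjusted p of 0.0372 and an adjusted p of 0.517 with an estimated correlation (camera 0.120 and 0.0507 without Samples 2L and 5L). Of 12 pericyte genes 1 rose and 3 fell, and of 11 thalamic genes 2 rose and 2 fell (2 and 1 adjusted over the list alone). In the choroid plexus list 2 of 12 rose, among them Kcne2, a potassium channel subunit, with 3 saline counts and a ratio of 44.3 (95% counting interval 14.8 to 217).

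Of 29 dopamine, serotonin and opioid genes 4 rose and 3 fell (1 and 3 adjusted over the list alone), with Oprk1, the kappa opioid receptor, higher (1.10) and Th, tyrosine hydroxylase, lower (-1.65). Of 9 cytochrome and nicotine metabolism genes 3 rose, among them Cyp1b1 (1.56), and Fmo1 fell (-1.88). Of 20 cell cycle genes 3 rose and 2 fell, 0 adjusted over the list alone. Of 11 newborn neuron and dentate genes 4 fell and 0 rose (camera adjusted p = 0.109, and 0.0480 and 0.0434 without Samples 7L and 8L, where the adjusted p with an estimated correlation was 0.467 and 0.482 and fry gave 0.0615 and 0.0418). Of 80 ribosomal protein genes 10 fell and 1 rose (6 and 1 adjusted over the list alone), with a camera adjusted p of 0.00945 and an adjusted p of 0.797 with an estimated correlation (camera 0.0626 and 0.0990 without Samples 2L and 3L, fry 0.277 with all). Of 23 mitochondrially encoded genes 3 rose and 2 fell (1 and 2 adjusted over the list alone), with a camera adjusted p of 0.6252, and of 0.0289 without Sample 3L (adjusted p = 0.538 there with an estimated correlation). Among Y-linked genes Ddx3y rose (0.79) while Uty (-0.45) and Kdm5d (-0.31) fell, and the X-linked partner Ddx3x rose by a similar size (0.77).

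In hippocampus the camera adjusted p of the lists not called ran from 0.0535 for oligodendrocyte genes to 0.956 for blood genes. Of these, the interferon (adjusted p = 0.000396), antigen presentation (0.0166) and astrocyte lists (0.00603) were called higher without saline 2. Oligodendrocyte genes were called higher without any 1 of saline 1, 2, 3 or 6 or nicotine 3 or 6 (3.25e-06 to 0.0473), and immediate early genes without saline 5 (0.00945). Called lower were newborn neuron and dentate genes without saline 1 or nicotine 2 or 5 (0.0260 to 0.0434), and meningeal genes without saline 1 or nicotine 5 or 6 (0.0104 to 0.0434). So were cell cycle genes without saline 5 or nicotine 2 (0.0369 and 0.0434) and choroid plexus genes without nicotine 5 (0.0275). With an estimated correlation none of these calls held (adjusted p = 0.689 to 1.00). Adjusted over the list alone, Lcn2 was higher with nicotine (2.66, from 0.141 to 0.872 CPM) in 3 lists, while Cebpd, a transcription factor, was lower in the glucocorticoid list (-0.49). The dentate genes Tdo2 (-0.71) and C1ql2 (-0.54) were lower adjusted over the list alone. None of these passed over all genes with edgeR, where 0 genes passed and 1577 stood at unadjusted p under 0.05 (DESeq2 15, limma-voom 0). Tshz2 (0.70) and Meis2 (0.50), transcription factor genes of forebrain neurons, had positive values that did not pass with edgeR.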
